A study of Mus musculus with 6 samples.

How the data were processed

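Libraries were made from total RNA of the right striatum of C57BL/6 mice, 3 after a sham operation and 3 after BCAS, with TRIzol extraction and an NEBNext Ultra kit for Illumina, per the labels' protocols. The deposited values are whole-number counts of reads per gene, made by the authors with featureCounts, per the file headers. The file headers name version 2.0.3 and the GENCODE vM20 annotation, whereas the submitters' processing notes list featureCounts 1.6.3, HISAT2, FastQC, Trim Galore, SAMtools 1.9, DESeq2 1.16.1 and the mm10 build. Per the file headers, reads were counted over exons and summed by gene in paired-end mode with no option for strand and none for counting pairs. Both mates of a pair can therefore add to a count, and reads from a gene and from an antisense or overlapping gene cannot be told apart. By the counter's defaults, reads that match several places or several genes were left out, which lowers near-identical copies such as C4a and C4b, the alpha globin genes and the class I genes. No exon overlap with another gene was found for C4b, Gfap, Drd1 or Cst7, while 14.3% of the exon length of Penk, 38.4% of Rarb, 63.5% of Trf, 43.5% of Gbx2 and 33.6% of Rarres2 overlapped another gene.

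All 54752 genes were read, and 54723 identifiers matched a symbol of the GENCODE M21 names when version suffixes were ignored. Groups and replicate numbers were taken from the sample titles. The deposited count files number the BCAS libraries 2 to 4 where the titles number them 1 to 3, in the same order, and each file was assigned by its sample record. Library totals ranged from 38033310 to 44937673 counted reads. A floor of 3 counts stood for 0.0681 to 0.0778 CPM, depending on the library. Counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of 16.9 or more), so that none was counted as a repeat of another.

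Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19039. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust, otherwise at its defaults, and glmQLFTest), with BCAS against sham and no covariate. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. Standard errors and fold changes come from the same fit, and levels are TMM-normalised CPM. The common biological coefficient of variation was 0.214. An exact test of 3 against 3 values cannot go below p = 0.1, two-sided, and was not used. A fold against a group with 0 counts was computed against a floor of 3 counts over the group. For 1 to 3 counts the ratio is given with a 95% exact binomial interval.

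Gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. There were 35 lists of cell type markers and pathways, covering microglia, complement, interferon response, antigen presentation, cytokines, astrocytes, oligodendrocytes, projection neurons, interneurons, synapses, immediate early genes, hypoxia, stress responses, the circadian clock, vessels, meninges, matrix, choroid plexus, ependyma, neighbouring regions, stem cells, blood, leukocytes, border macrophages and mitochondria. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, which called 21 (13 higher, 8 lower). With a correlation estimated from the data camera called 0 of 35 lists. With fry, which asks whether a list moves on balance in 1 direction, 6 were called: the direct, indirect and shared projection neuron, interneuron, synaptic and nuclear oxidative phosphorylation lists. Named genes were the 12 largest rises and 12 largest falls among called genes with a symbol other than a predicted model and groups that did not overlap, up to 4 members with the smallest p of each called list, and 12 genes in any case: Gfap, Aif1, Cx3cr1, C4b, Drd1, Drd2, Penk, Ppp1r1b, Mbp, Vegfa, Cldn5 and Fos.

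The fits were tested on simulated data. For the comparison of BCAS with sham, counts of 18380 genes were drawn from the sham means, the library sizes and the dispersions, with 200 genes changed. The test recovered 64% of the 2-fold and 84% of the 4-fold changes, and 12 of its 160 calls (7.5%) were of unchanged genes. In a simulated set test a list shifted by 2-fold was called, and 1 of 34 unshifted lists. Genes were drawn independently there, whereas the estimated correlation within lists reached 0.970 in the data (disease-associated microglia). The simulation therefore does not test the error of camera at a preset correlation of 0.01 on these lists.

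Alternatives were scaling by DESeq2 size factors or by library size only, no low-count filter, a minimum of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom (limma 3.58.1), each library left out in turn, the replicate number as a block, thinning to the smallest library, and the other list tests. After the data were seen, halved counts and a fit without Sham 1 and BCAS 3 were added. The fixed alternatives left out single libraries in edgeR only. DESeq2 and limma-voom fits with 1 library left out were not among them. Exon overlap was computed with GenomicRanges 1.54.1 from the exon coordinates in the count files. Chromatin accessibility data were not used here. The value of 1 named gene of the neural stem cell and neuroblast list is not reported here.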

Results

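Messenger RNA was counted by sequencing in the right striatum of C57BL/6 mice after bilateral carotid artery stenosis (BCAS), an operation that narrows both carotid arteries and lowers blood flow to the forebrain, or after a sham operation. There were 3 BCAS and 3 sham libraries, all labelled 14 weeks, and the labels do not state whether this is age or time after surgery. Each library held 38033310 to 44937673 counted reads. Mitochondrially encoded genes took 8.79% to 10.7% of the reads, and the libraries of both groups overlapped in this share. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples. The question of the comparison was which transcripts of the striatum differ after lasting low blood flow.

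Genes of activated microglia, complement, interferon signalling and reactive astrocytes were higher after BCAS, and genes of striatal projection neurons were lower. Cst7, a cysteine protease inhibitor of activated microglia (ENSMUSG00000068129.5, mm10 chromosome 2, 150570415 to 150578944), went from 0.164 ± 0.174 to 133 ± 93.2 CPM (SD, n = 3 per group). Gfap, the intermediate filament of astrocytes (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912), went from 139 ± 26.8 to 2622 ± 1654 CPM, an 18.8-fold rise. Drd1, the D1 dopamine receptor (ENSMUSG00000021478.6, chromosome 13, 54051183 to 54055705), went from 240 ± 14.8 to 115 ± 28.0 CPM. Of 19039 genes tested, 1407 were higher and 904 lower in BCAS at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among these, 839 rose and 120 fell by 2-fold or more. Higher genes made up 60.9% of the calls, and 72.1% when libraries were scaled by library size only. The groups did not overlap at 6865 genes (36.1%, where chance gives 10%), including all 2311 called genes. The number of edgeR calls depended on which libraries were in the fit, and was 0 without Sham 1, Sham 2, Sham 3 or BCAS 2. In those fits 3948 to 5784 genes had an unadjusted p below 0.05 in edgeR, against 5772 with all libraries. DESeq2 called 2000 to 3531 genes there and limma-voom 0. They had 3 residual degrees of freedom against 4, so 0 calls does not by itself show that 1 library carried the differences. With 0 genes called, no member of any list could pass in those edgeR fits. Without BCAS 3, the library with the smallest glial rise, edgeR called 2616 higher and 1351 lower genes.

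**Figure D1:**
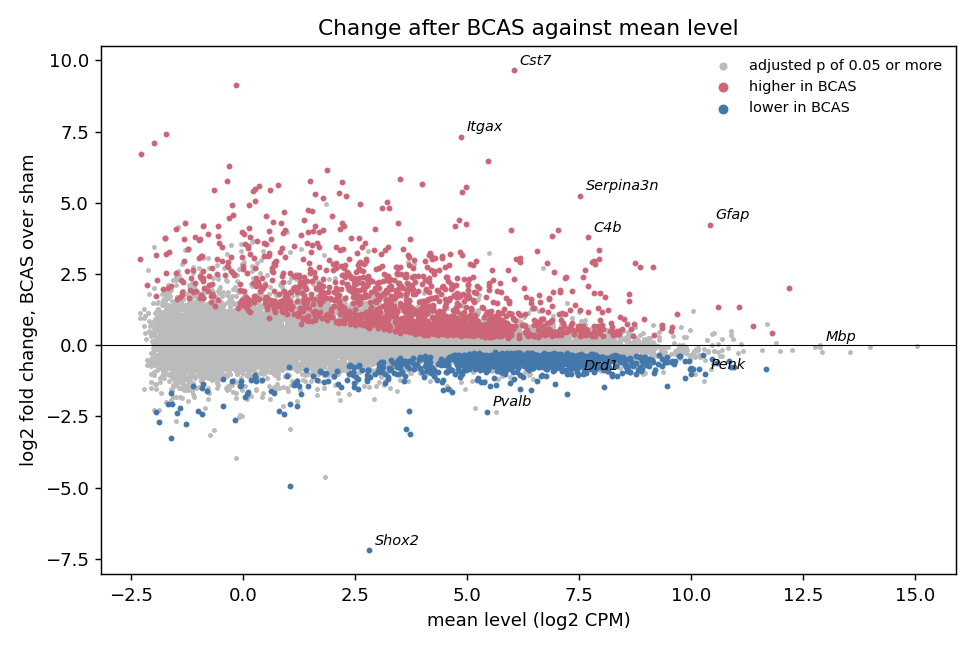
Each point is 1 of 19039 genes, with its mean level in log2 CPM on the horizontal axis and its log2 fold change, BCAS over sham, on the vertical axis. Red points are the 1407 genes called higher and blue points the 904 called lower, and Cst7 has the highest log2 fold change at 9.67.

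Microglial genes rose together. Of 21 tested genes of disease-associated microglia, the state described around lesions and plaques, 18 rose and 0 fell, with a median log2 fold change of 2.92 (20 rose when adjusted over the list alone). Beside Cst7, Itgax, an integrin chain, rose 160-fold, from 0.355 ± 0.189 to 57.8 ± 44.5 CPM. Clec7a, a receptor for fungal glucans, rose 89.0-fold, and Cd52, a surface glycoprotein of leukocytes, rose 18.2-fold. Of 13 genes of homeostatic microglia, 10 rose, with a median of 1.82 (13 when adjusted over the list alone). Fcrls rose 7.42-fold, Aif1, which encodes the microglial marker Iba1, 4.90-fold, Olfml3 4.04-fold and Cx3cr1, the fractalkine receptor, 3.78-fold. The lists differed from other genes by camera with its preset correlation (adjusted p = 3.89e-28 for disease-associated and 1.35e-11 for homeostatic microglia), and both calls were lost with adjusted p = 0.266 with an estimated correlation. Fry called neither (adjusted p = 0.073 and 0.086), nor any other glial or immune list. The disease-associated microglia genes lay 4.19, 3.51 and 2.15 log2 units above the sham mean in BCAS 1, 2 and 3. No member passed in edgeR without Sham 1, Sham 2, Sham 3 or BCAS 2, where Cst7 had adjusted p of 0.0510 to 0.126, while DESeq2 called 19 to 21 disease-associated genes with any 1 library left out. With all libraries limma-voom called 13 disease-associated and 7 homeostatic genes higher. With the replicate number as a block, edgeR called 13 and 1.

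Complement, interferon and antigen presentation genes rose as well. Of 12 complement genes, 10 rose (10 when adjusted over the list alone), with a median log2 fold change of 2.86. C4b, a component of the classical pathway, rose 13.9-fold, from 27.8 ± 5.75 to 387 ± 174 CPM. C3, the central complement component, rose 47.3-fold, and C1qa and C1qb, subunits of the initiating complex, 8.07-fold and 7.25-fold. Of 20 interferon response genes, 18 rose (20 when adjusted over the list alone), with a median of 2.11. Irf7, a transcription factor of the interferon response, rose 6.54-fold, Usp18 6.48-fold, Ifi44 5.89-fold and Rtp4 5.07-fold. Of 14 antigen presentation genes, 9 rose (13 when adjusted over the list alone), with a median of 2.47, among them the class I genes H2-D1 (7.82-fold), B2m (6.78-fold) and H2-K1 (5.87-fold) and the immunoproteasome subunit Psmb8 (6.13-fold). The class II genes H2-Aa, H2-Ab1 and H2-Eb1 stood at 2.94, 2.86 and 2.38 on the log2 scale without passing (adjusted p = 0.118, 0.105 and 0.115, edgeR). Cd74 (3.24, 0.0553) and Ciita (0.73, 0.403) did not pass either. Reads shared by C4b and its near-identical copy C4a, or by class I genes, were not counted, so their levels are uncertain. Camera with its preset correlation called the lists (adjusted p = 9.0e-14, 7.2e-24 and 7.0e-12), and each call was lost with adjusted p = 0.266 with an estimated correlation. Without Sham 1, Sham 2, Sham 3 or BCAS 2 no gene at all passed in edgeR, while the log2 fold change of C4b stayed at 3.57 to 4.13 with any 1 library left out. DESeq2 then called 10 to 12 complement, 19 to 20 interferon and 9 to 13 antigen presentation genes. With all libraries limma-voom called 4, 12 and 4 of them.

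Of 18 cytokine and chemokine signalling genes, 12 rose (16 when adjusted over the list alone), with a median log2 fold change of 3.15, also 3.15 with Tnf at its bound. Ccl3, a chemokine of activated microglia and macrophages, rose 57.5-fold, from 0.386 ± 0.181 to 22.3 ± 13.2 CPM, Ccl4 rose 54.7-fold, Ccl12 16.1-fold and the inflammatory protease Casp1 7.36-fold. Tnf had 0 counts in all sham libraries and 62 in the BCAS libraries, which makes it at least 21.2-fold higher, against a floor of 3 counts over the group. Of 11 genes of infiltrating leukocytes, 4 rose (6 rose and 1 fell when adjusted over the list alone), with a median of 2.34. They were the T cell genes Cd3g (30.6-fold) and Cd8a (11.8-fold), the cytotoxic granule gene Nkg7 (8.84-fold) and the monocyte gene Ly6c2 (13.8-fold), all with a mean of 2.02 CPM or less in BCAS. Limma-voom called none of the 11, and DESeq2 called 8 higher and 1 lower of 13. The leukocyte list lay 2.49 and 2.08 log2 units above the sham mean in BCAS 1 and BCAS 2 and 0.16 above it in BCAS 3. The blood list, with 0 of 5 genes called, lay 1.32 above the sham mean in BCAS 1 and at -0.70 in BCAS 3. Camera called the cytokine list (adjusted p = 1.1e-14, and 0.266 with an estimated correlation) and the leukocyte list (adjusted p = 0.00851, and 0.570 with an estimated correlation), and did not call the blood list (adjusted p = 0.779). The leukocyte list was not called among genes of at least 1 CPM in 3 libraries (median -0.19, adjusted p = 0.552, camera), with limma-voom weights (0.0574) or with halved counts (0.421). Without BCAS 1 2 leukocyte genes rose, and without BCAS 3 8 rose and 1 fell. Without Sham 1, Sham 2, Sham 3 or BCAS 2 no member of any of these lists passed in edgeR, while the log2 fold change of Ccl3 stayed at 5.33 to 6.26 and DESeq2 called 14 to 18 cytokine genes with any 1 library left out. With all libraries DESeq2 called 17 and limma-voom 6 cytokine genes.

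The other rises among the 12 largest were of low-count genes. Atp6v0d2, a subunit of the vacuolar proton pump, had 0 counts in sham and 202 in BCAS, at least 69.2-fold higher against the floor of 3 counts over the group. Ighv8-8, an immunoglobulin segment, and Klrb1a, a receptor of natural killer cells, also had 0 counts in sham and were at least 17.1-fold and 13.01-fold higher. Cd200r4 had 2 counts in sham and 178 in BCAS, a ratio of 91.4 with a 95% counting interval of 24.9 to 761. Cd244a had 3 and 172 counts, a ratio of 58.9 with an interval of 19.8 to 288. Ch25h, which makes 25-hydroxycholesterol, rose 71.8-fold, from 0.0955 ± 0.0974 to 7.10 ± 4.84 CPM. Both mates of a pair were counted, so these intervals are too narrow, the floor stands for fewer than 3 fragments and the bounds would be lower for counted fragments. In edgeR none of these genes passed without Sham 1, Sham 2, Sham 3 or BCAS 2.

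Astrocyte genes rose in both the reactive and the general list. Of 15 reactive astrocyte genes, 9 rose (12 when adjusted over the list alone), with a median log2 fold change of 2.69. Serpina3n, a secreted protease inhibitor, rose 38.01-fold, from 9.45 ± 1.59 to 359 ± 212 CPM, Tgm1, a transglutaminase, 52.55-fold, and Cd109 6.44-fold. Gfap reached 3900, 3212 and 754 CPM in BCAS 1, 2 and 3. Of 12 general astrocyte genes, 4 rose (10 when adjusted over the list alone), with a median of 0.68. They were the water channel Aqp4 (3.23-fold), the glutamate transporter Slc1a3 (2.15-fold), the transcription factor Sox9 (2.11-fold) and the gap junction gene Gja1 (1.96-fold). Camera with its preset correlation called both lists (adjusted p = 4.5e-12 and 5.4e-08), and the calls were lost with adjusted p = 0.266 and 0.316 with an estimated correlation. Without BCAS 1 Aqp4 did not pass (adjusted p = 0.0590, edgeR). Without BCAS 3, 11 of the 12 general astrocyte genes rose, and without Sham 1, Sham 2, Sham 3 or BCAS 2 no member of either list passed in edgeR, while the log2 fold change of Gfap stayed at 3.83 to 4.67 and DESeq2 called 9 to 13 reactive and 4 to 12 general astrocyte genes with any 1 library left out. With all libraries DESeq2 called 12 and 9, and limma-voom 4 and 3.

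**Figure D2:**
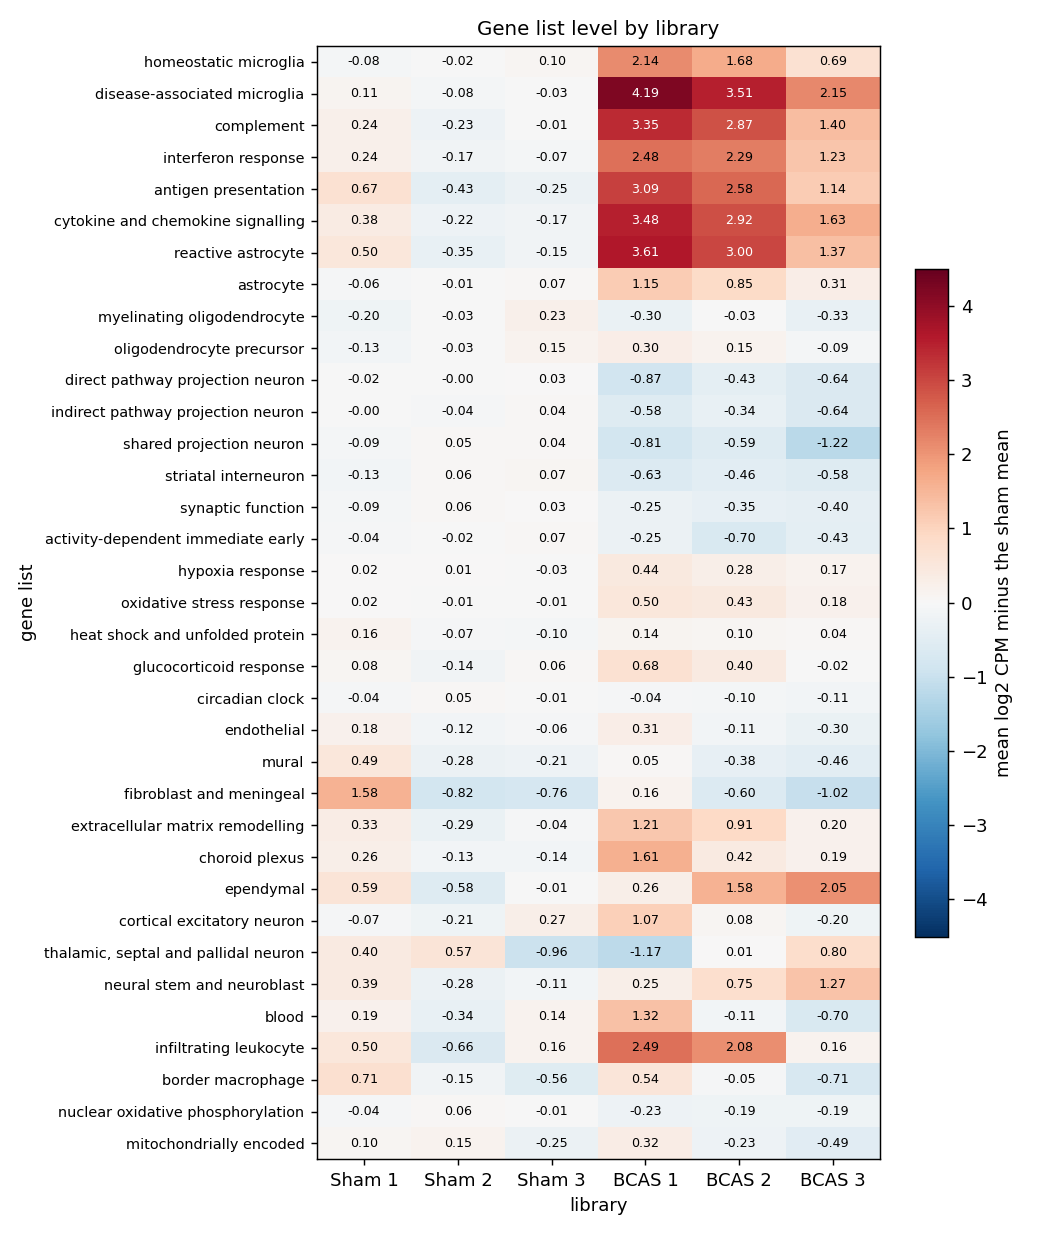
Each cell is the mean log2 CPM of a gene list in 1 library minus the mean of the 3 sham libraries, with red above and blue below it. The disease-associated microglia list stands at 4.19, 3.51 and 2.15 in the BCAS libraries and the shared projection neuron list at -0.81, -0.59 and -1.22, and neighbouring-region lists such as ependymal and cortical excitatory neuron differ between single libraries.

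Genes of striatal projection neurons fell. Of 18 genes shared by both projection neuron classes, 12 fell and 0 rose, with a median log2 fold change of -0.85 (16 fell when adjusted over the list alone). Arpp21, a phosphoprotein regulated by dopamine signalling, fell by 0.85 on the log2 scale, from 1353 ± 71.1 to 749 ± 99.97 CPM. Falls were also called for Ppp1r1b, which encodes DARPP-32 (-0.84), the G protein subunit gene Gnal (-0.67) and the phosphatase Ptpn5 (-0.58). The retinoic acid receptor Rarb (-1.10), of whose exons 38.4% overlap another gene, was called lower too. Of 8 direct pathway genes, 4 fell (4 when adjusted over the list alone), with a median of -0.63: Slc35d3 (-1.30), Drd1 (-1.06), Tac1, the substance P precursor (-0.85), and the muscarinic receptor Chrm4 (-0.76). Of 7 indirect pathway genes, 3 fell (4 fell and 1 rose when adjusted over the list alone), with a median of -0.83. Penk, the enkephalin precursor (ENSMUSG00000045573.9, chromosome 4, 4133531 to 4138819), fell by 1.02, from 1710 ± 26.5 to 845 ± 142 CPM. The receptor Gpr6 (-0.83) and the D2 dopamine receptor Drd2 (-0.87) fell, while Adora2a, at -0.94, did not pass (adjusted p = 0.0631, edgeR).

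Camera with its preset correlation called the shared, direct and indirect lists lower (adjusted p = 4.6e-15, 3.3e-06 and 0.00058), and each call was lost with adjusted p = 0.266 with an estimated correlation. Fry called all of them (adjusted p = 0.035, 0.025 and 0.025). The shared projection neuron genes lay at -0.81, -0.59 and -1.22 log2 units from the sham mean in BCAS 1, 2 and 3. In the same libraries genes of neighbouring tissue were uneven: the cortical list lay at 1.07 in BCAS 1 and the ependymal list at 1.58 in BCAS 2 and 2.05 in BCAS 3. Without Sham 1, Sham 2, Sham 3 or BCAS 2 no projection neuron gene passed in edgeR, where Drd1 had adjusted p of 0.0522 to 0.126, and Ppp1r1b was also lost without BCAS 1 (0.0686), while DESeq2 called 14 to 17 of the 18 shared genes lower with any 1 library left out. With all libraries limma-voom called 10 shared, 4 direct and 2 indirect genes lower. With the replicate number as a block, edgeR called 2, 3 and 2.

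Some interneuron, synaptic and activity-dependent genes also fell, while most members of these lists did not pass. Of 13 interneuron genes, 5 fell (8 when adjusted over the list alone), with a median log2 fold change of -0.63. Pvalb, the calcium buffer of fast-spiking interneurons, fell by 2.34, from 72.3 ± 20.5 to 14.3 ± 8.06 CPM. Th, which makes dopamine precursors (-1.12), the cholinergic transporter gene Slc18a3 (-0.82) and the receptor Kit (-0.63) fell too. Of 20 synaptic genes, 6 fell (10 when adjusted over the list alone), with a median of -0.36, including the glutamate receptor subunits Grin2b (-0.74) and Grin1 (-0.49), Camk2b (-0.57) and the vesicle fusion gene Snap25 (-0.63). Of 15 immediate early genes, 6 fell (7 when adjusted over the list alone), with a median of -0.52: Arc (-1.08), Npas4 (-0.95), Egr3 (-0.83) and Egr1 (-0.73) were among them. Fos did not pass (log2 fold change 0.02, adjusted p = 0.969, edgeR), and stood at -0.17 without BCAS 1 and 0.20 without BCAS 3. Of 20 nuclear genes of oxidative phosphorylation, 3 fell (5 when adjusted over the list alone), with a median of -0.20: Atp5b (-0.35), Cox5a (-0.33) and Ndufb8 (-0.28), while Ndufs1 stood at -0.34 without passing. Camera called these lists lower (adjusted p = 1.5e-05, 1.4e-06, 2.8e-05 and 0.00013), and each call was lost with adjusted p = 0.266 with an estimated correlation. Fry called the interneuron, synaptic and oxidative phosphorylation lists (adjusted p = 0.025 each) and not the immediate early list (0.069). Without Sham 1, Sham 2, Sham 3 or BCAS 2 no member passed in edgeR, while the log2 fold change of Grin2b stayed at -0.84 to -0.66. DESeq2 with any 1 library left out called 6 to 9 interneuron, 6 to 15 synaptic, 6 to 9 immediate early and 0 to 9 oxidative phosphorylation genes lower. With all libraries it called 8, 9, 7 and 4, and limma-voom 4, 5, 5 and 1. Without BCAS 1 0 oxidative phosphorylation and 3 interneuron genes fell, with Pvalb (0.0541) and Th (0.0507) lost, and without BCAS 3 8 interneuron and 10 synaptic genes fell.

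**Figure D3:**
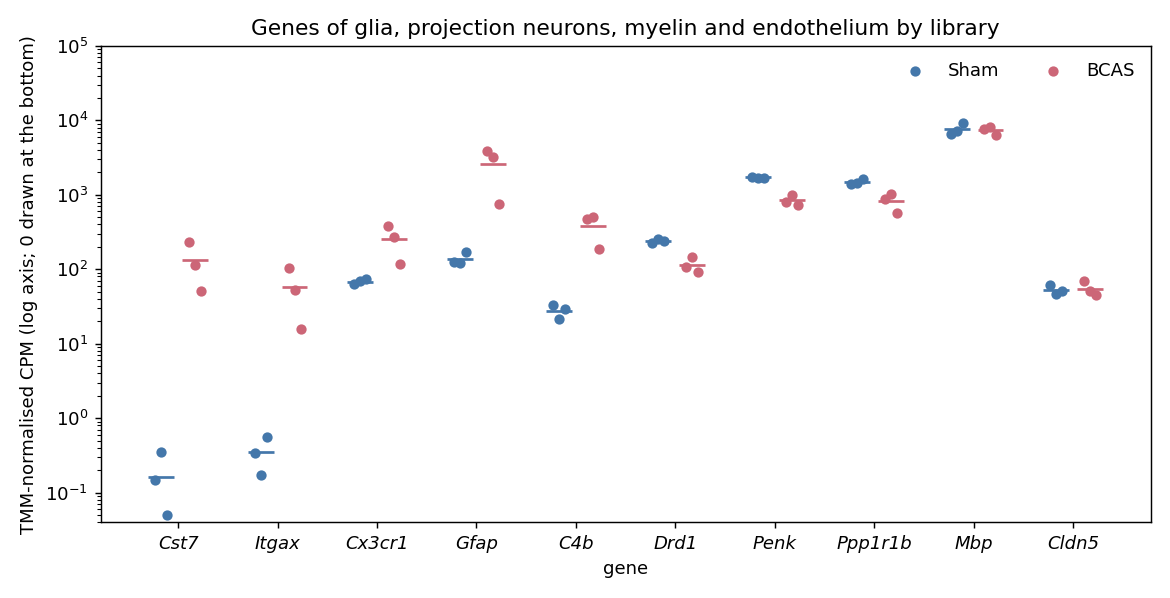
Points are the TMM-normalised CPM of single libraries on a log axis, blue for sham and red for BCAS, lines are group means of 3 libraries, and a value of 0 is drawn at the bottom of the axis. Cst7, Itgax, Cx3cr1, Gfap and C4b lie higher and Drd1, Penk and Ppp1r1b lower in every BCAS library, while Mbp and Cldn5 overlap.

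Myelin and vascular genes showed no called change in edgeR with all libraries. Of 15 genes of myelinating oligodendrocytes 0 passed (0 when adjusted over the list alone), with a median log2 fold change of -0.27. Mbp, the myelin basic protein gene, stood at 7690 ± 1442 CPM in sham and 7409 ± 902 in BCAS, Mal at -0.55, Ermn at -0.45 and Ugt8a at -0.44, and Trf, of whose exons 63.5% overlap another gene, at 0.44. Camera called the list lower (adjusted p = 0.0104, and 0.678 with an estimated correlation), a call lost without BCAS 3 (0.115), where 1 myelin gene rose and 1 fell. Of 11 oligodendrocyte precursor genes 1 rose, C1ql1 at 0.88, named after its value was seen, and the list was not called (adjusted p = 0.718, camera). None of 14 endothelial genes (median -0.07) or 12 mural genes (median 0.06, mean -0.36, lowest -2.33, highest 0.45) passed. Without BCAS 1 edgeR called 1 mural gene lower. The tight junction gene Cldn5 stood at 53.2 ± 7.87 and 54.6 ± 12.5 CPM. Both lists were not called (adjusted p = 0.513 and 0.626, camera). DESeq2 called 2 myelin genes lower and 0 endothelial or mural genes, and limma-voom called 0 in all of these lists but the precursors, where it called 1. With 1 library left out DESeq2 called 0 to 4 myelin genes lower (4 without Sham 1 or BCAS 2) and 1 higher without BCAS 3. It called 2 endothelial genes lower without BCAS 1 and 1 higher without Sham 1, and 0 to 2 mural genes lower (2 without Sham 2).

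Of 18 hypoxia response genes, 3 rose and 1 fell (3 and 1 when adjusted over the list alone), with a median log2 fold change of 0.11, and the list was not called (adjusted p = 0.331, camera). The members called were the hexokinase Hk2 (2.38), the prolyl hydroxylase Egln3 (1.72) and the kinase Pdk1 (0.67), which rose, and the mitophagy gene Bnip3, which fell by 0.39, all 4 named after their values were seen. Vegfa, the vascular growth factor, did not pass (log2 fold change -0.01, adjusted p = 0.983, edgeR), and its sign was positive when libraries were scaled by library size only. Of 17 extracellular matrix remodelling genes, 3 rose (6 when adjusted over the list alone), with a median of 0.33. The macrophage elastase Mmp12 rose 47.7-fold, Tgfb1 3.77-fold and Timp2 1.66-fold, and Timp1 stood at 3.38 without passing. Camera called the matrix list (adjusted p = 0.0153, and 0.570 with an estimated correlation). Without Sham 1, Sham 2, Sham 3 or BCAS 2 no member of either list passed in edgeR, and without BCAS 3 10 matrix genes rose and 1 fell, and 6 hypoxia genes rose and 2 fell. Without BCAS 1 4 hypoxia genes rose and 0 fell, and DESeq2 called 3 higher and 0 lower without Sham 2 or Sham 3, so the fall of Bnip3 was lost there. DESeq2 called 7 and limma-voom 1 matrix gene higher. Without BCAS 1 the list extracellular matrix remodelling (adjusted p = 0.0903, camera) and Tgfb1 (0.0523, edgeR) were not called.

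Lists of tissue that borders the striatum differed between single libraries. Of 9 ependymal genes, which mark the ciliated lining of the ventricles, 1 rose, Foxj1 at 2.29-fold (5 when adjusted over the list alone), with a median log2 fold change of 1.43, and Cfap126, Tekt1 and Rarres2 stood at 1.46, 1.33 and 1.15 (33.6% of the exons of Rarres2 overlap another gene). Of 12 choroid plexus genes 1 rose, Sostdc1 at 2.51-fold (3 when adjusted over the list alone), with a median of 1.20, and Otx2, Folr1 and Calml4 stood at 1.35, 1.22 and 1.02. Of 12 neural stem cell and neuroblast genes 1 rose, Cdk1 at 3.69-fold (3 when adjusted over the list alone), with a median of 0.77, and Igfbpl1 and Mki67 stood at 1.82 and 0.71. Camera called the ependymal, choroid plexus and stem cell lists (adjusted p = 0.00036, 0.0270 and 0.00847), and the calls were lost with adjusted p = 0.513, 0.513 and 0.570 with an estimated correlation. DESeq2 called 6, 4 and 3 of their genes and limma-voom 1 in each. Without BCAS 1, 7 ependymal genes and 4 stem cell genes rose, and the list choroid plexus was not called (adjusted p = 0.226, camera, median 0.11). Without BCAS 3 the list ependymal, the list choroid plexus and the list neural stem and neuroblast were not called (adjusted p = 0.115, 0.0910 and 0.441, camera). The cortical list (1 of 12 genes rose, Fezf2, and 1 fell, Lamp5) and the fibroblast and meningeal list (0 of 12) were not called (adjusted p = 0.666 and 0.162, camera), and the latter stood at 1.58 in Sham 1 against -0.82 and -0.76 in Sham 2 and Sham 3.

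Of the 12 genes with the largest falls, 8 were more than 1 log2 unit higher in Sham 1 and Sham 2, on average, than in Sham 3. Shox2, a homeobox gene (ENSMUSG00000027833.16, chromosome 3, 66971727 to 66981771), fell by 7.20 on the log2 scale (adjusted p = 0.0297, edgeR), with 11.9, 28.3 and 1.22 CPM in the sham libraries and 0, 0.259 and 0.0227 CPM in BCAS. Its call was lost with each library left out in turn, with adjusted p of 0.0613 to 0.141 in edgeR. Abhd12b, Tnnt1, Ramp3 and Fam19a4 likewise did not pass whichever library was left out. Rab37 passed only without BCAS 1, and Trim40, Ifi27l2b and Pvalb only without BCAS 3. Abhd12b (-4.94), Rab37 (-3.13), the slow troponin gene Tnnt1 (-2.95) and the receptor-modifying gene Ramp3 (-2.32) fell, each with its highest levels in Sham 1 and Sham 2. Trim40 (-2.77), Fbxo40 (-2.62) and Fam19a4 (-2.41) fell and were also highest there. CT009580.1 (-3.27), Ifi27l2b (-2.42) and Agmat (-2.31) fell too, all below 1 CPM in every library. The list of thalamic, septal and pallidal genes, with Tnnt1 and Gbx2 (-1.19, with 43.5% of its exons overlapping another gene) of 12 called lower (2 when adjusted over the list alone), stood at 0.40, 0.57 and -0.96 in Sham 1, 2 and 3 and at -1.17, 0.01 and 0.80 in BCAS 1, 2 and 3, and was not called (adjusted p = 0.342, camera, median -0.48, mean 0.04). Without BCAS 1 3 of its genes rose and 0 fell, and without BCAS 3 0 passed. DESeq2 called 1 higher and 3 lower, and limma-voom 0.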

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

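The fits with halved counts and without Sham 1 and BCAS 3 were chosen after the results were seen. DESeq2 called 2208 genes higher and 1445 lower. Limma-voom called 684 higher (52.0% of its calls), 631 lower and 419 by 2-fold or more. With the replicate number as a block, edgeR called 378 higher, 155 lower and 339 by 2-fold or more. Deviations of same-numbered libraries correlated at 0.03, -0.04 and -0.04, which gives no sign that the numbers pair the samples. Pairing is not excluded, since differences between single libraries in neighbouring tissue can hide it. Leaving out 1 library gave 0 to 2616 higher, 0 to 1351 lower and 0 to 1511 genes by 2-fold or more. EdgeR called 0 without Sham 1, Sham 2, Sham 3 or BCAS 2, with smallest adjusted p of 0.0510, 0.126, 0.105 and 0.0564. All fits without 1 library had 3 residual degrees of freedom, and the median prior degrees of freedom were 2.83 to 3.06 in these and 4.15 and 5.25 without BCAS 1 and BCAS 3. At an unadjusted p below 0.05 these had 5784, 3948, 4393 and 4472 genes, and DESeq2 called 3531, 2000, 2276 and 2429. Without BCAS 1 edgeR called 1143 higher and 761 lower. Without Sham 1 and BCAS 3 together edgeR called 2772 higher, 1655 lower and 1690 by 2-fold or more. Sham 1 was highest in meningeal genes and BCAS 3 in ependymal genes, but BCAS 1 was highest in cortical genes, and BCAS 3 also had the smallest glial rise. The other scalings, filters, thinning and halving kept each count within 1.5 times. Camera called 18 to 23 lists in every fit at its preset correlation, 0 with an estimated correlation and 6 by fry. Without BCAS 1 and BCAS 3, 18 and 7 named genes lost their call. All 87 called named genes lost their call in at least 1 setting. This had to happen, since edgeR called 0 genes without Sham 1, Sham 2, Sham 3 or BCAS 2, and it does not rank these genes. In all settings 103 of 107 named genes kept their sign. The 4 that did not were uncalled. Fos was at -0.0049 with DESeq2 size factors, -0.0107 with DESeq2, -0.0156 with limma-voom, -0.000577 with the block and -0.171 to 0.198 without 1 library. Vegfa was at 0.0383 by library size only, 0.00326 with 1 CPM in 3 libraries, 0.103 without Sham 1 and BCAS 3 and -0.147 to 0.0946 without 1 library. Without 1 library Cldn5 ranged from -0.159 to 0.162 and Mbp from -0.156 to 0.105. The list infiltrating leukocyte turned to -0.194 with 1 CPM in 3 libraries (adjusted p = 0.552 by camera, 1.73e-05 to 0.570 over all settings). The list blood was called lower without BCAS 1 (-0.478, adjusted p = 0.0463 by camera, up to 0.919 over all settings) and stood at 0.628 without BCAS 3. The cause of these changes was not tested. Depth limits genes near 3 counts, such as Tnf and Cd200r4.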

Other observations

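The tests of the patterns were chosen after the results were seen, except the test of the second thalamic list, which was written before its values were seen. Of 14 oxidative stress genes 3 rose and 2 fell (4 and 3 when adjusted over the list alone): Hmox1, the heme oxygenase (2.13), and the metallothioneins Mt1 (1.15) and Mt2 (1.82, with 73.5% of its exons overlapping another gene) rose, and Srxn1 (-0.40) and Sod2 (-0.35) fell, with no list call (adjusted p = 0.115, camera). Of 14 glucocorticoid response genes 2 rose and 3 fell (2 and 3 when adjusted over the list alone): Lcn2 (5.66), also a reactive astrocyte gene, and the phagocytic receptor Mertk (1.15) rose, and Tsc22d3 (-0.43), Ddit4 (-0.37) and Errfi1 (-0.36) fell (list adjusted p = 0.718, camera). Lcn2 stood at 69.5, 22.6 and 0.976 CPM in the BCAS libraries and at 0.198 to 0.827 in sham. Of 15 heat shock and unfolded protein genes Pdia4 rose (0.63) and Hsph1 fell by 0.54 (list adjusted p = 0.981, camera), a fall lost with limma-voom and without BCAS 1 (1 higher and 0 lower in each). Limma-voom called 0 glucocorticoid genes higher and 2 lower. These genes were named after their values were seen.

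Of 14 circadian clock genes 1 rose and 2 fell (3 and 4 when adjusted over the list alone): the repressor Bhlhe41 rose (0.53), and the activators Arntl (-0.59) and Npas2 (-0.44) fell, with no list call (adjusted p = 0.197, camera). Of 7 border macrophage genes 1 fell, the hemoglobin receptor Cd163, by 1.17, from 9.13, 10.3 and 8.55 CPM in sham to 5.15, 4.85 and 2.43 CPM in BCAS (list adjusted p = 0.463, camera). Of 13 mitochondrially encoded genes 1 fell, mt-Nd3, by 1.43 (list adjusted p = 0.229, camera). These genes too were named after their values were seen, and in edgeR none of the genes of these stress, clock and macrophage lists passed without Sham 1, Sham 2, Sham 3 or BCAS 2. DESeq2 without 1 of these called 3 to 4 oxidative stress genes higher and 1 to 3 lower, 2 glucocorticoid genes higher and 0 to 3 lower, and 1 to 3 heat shock genes higher and 0 to 1 lower. It called 0 to 1 clock genes higher (0 without BCAS 2) and 2 to 3 lower, 0 to 1 border macrophage genes higher and 1 lower, and 0 to 1 mitochondrially encoded genes higher and 1 to 2 lower. In edgeR, without BCAS 1 0 glucocorticoid response genes rose and 1 fell, and 2 oxidative stress genes rose and 1 fell. Without BCAS 3 1 mitochondrially encoded gene rose and 0 fell.

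The 12 largest falls included Shox2, Tnnt1, Rab37 and Ramp3, which were highest in Sham 1 and Sham 2. A second list of 8 thalamic markers (Lef1, Synpo2, Ntng1, Amotl1, Patj, Rgs16, Rora and Cacna1g) was higher in Sham 1 and Sham 2 than in Sham 3, by 1.26 ± 0.165 log2 units (SE over genes), which is in line with thalamic tissue in those 2 pieces. All 8 were also detected in every BCAS library, and Rora, the most abundant in sham, stood at 79.7, 135 and 54.9 CPM in sham and 47.6, 37.3 and 27.9 in BCAS, while Cacna1g stood at 30.9, 42.9 and 19.1 in sham and 32.2, 27.6 and 52.0 in BCAS. The fixed list of thalamic, septal and pallidal genes had its highest mean in BCAS 3 (0.80) and its lowest in BCAS 1 (-1.17), while its members Tnnt1 and Gbx2 were highest in Sham 1 and Sham 2. Lower expression in the striatum itself after BCAS stays open: the 12 genes had a mean gap between those sham libraries and Sham 3 of 1.44 ± 0.398, with 8 above 1 and Pvalb, Agmat, Ifi27l2b and CT009580.1 near or below 0.3, and which part of the falls each accounts for cannot be told apart with 3 sham libraries.

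Genes of projection neurons, such as Drd1, Penk and Ppp1r1b, fell while glial genes rose. Dilution by added glial RNA would lower other cell types alike. The gap between endothelial and precursor genes and shared projection neuron genes widened in BCAS by 0.91 ± 0.178 log2 units (SE over libraries). These 2 reference lists were chosen after the results as cell types without a response, so the gap largely restates the projection neuron fall. The myelinating oligodendrocyte list moved down, at a median of -0.27, against -0.85 for the shared projection neuron list. In BCAS 1, 2 and 3 the myelinating list lay at -0.30, -0.03 and -0.33 log2 units from the sham mean. The shared projection neuron list lay at -0.81, -0.59 and -1.22. The fibroblast and meningeal list had a median of -0.92, but was uneven within sham. The myelin values argue against dilution as the whole cause of the projection neuron fall, unless myelin genes rose by themselves, which was not tested. Dilution as a part of the cause stays open. A smaller share of striatum in the BCAS pieces stays open: 3 of the 3 BCAS libraries had at least 1 of 4 neighbouring-region lists above the sham range, and each had 2. With 4 lists this can arise by chance. A smaller share would also lower striatal genes alike, but log2 fold changes ranged from -1.30 to 0.01 over the direct pathway list. They ranged from -1.02 to 0.47 over the indirect and from -1.25 to -0.25 over the shared list. Whether these genes are restricted to the striatum was not tested, so the ranges do not decide it. A loss of expression or of neurons after BCAS, dilution as a part of the cause and uneven dissection cannot be told apart.

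The disease-associated microglia genes lay 2.04 ± 0.131 log2 units higher in BCAS 1 than in BCAS 3 (SE over genes). A smaller share of striatum in BCAS 3 alone would move the projection neuron genes as much, but these differed by 0.41 ± 0.177, leaving 1.63 ± 0.220. BCAS 1 itself held cortical genes at 1.07 and choroid plexus genes at 1.61 above the sham mean, and its shared projection neuron genes lay at -0.81. The gap between these libraries therefore does not measure the striatal share of BCAS 3, and the errors are over genes, not samples. A smaller share of striatum in BCAS 3 stays open. The totals of these libraries were 40957890 and 40635546 counts. A candidate explanation is a difference between these samples in the response to the operation, which was not tested.

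The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1407 higher, 904 lower and 959 genes changed 2-fold or more, 1 split of 10 for each, and the highest other split gave 0. The real split gave 21 called lists at the preset correlation, and 2 of the 10 splits, itself included, gave as many. The other splits called 13 to 22 lists while they called 0 genes. The highest of them, with 22, set Sham 1, BCAS 1 and BCAS 2 against the rest. List calls at the preset correlation therefore do not set the real grouping apart.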
